A study of Homo sapiens with 9 samples.

How the data were processed

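RNA sequencing was done on HUES9 human embryonic stem cells. Per the labels, the cells were grown on mitomycin-treated mouse embryonic fibroblasts between passages 44 and 46, formed into embryoid bodies by centrifugation, and then plated on Matrigel. Total RNA was extracted with RNeasy columns and sequenced on an Illumina instrument. The 9 libraries were grouped by the labels into untreated day 1 cells, day 13 cells with 10 µM AA147 and day 13 cells with 10 µM RP22, with 3 replicates each that the labels call independent experiments. Libraries of cells with solvent alone were not analysed here, and reads from the mouse feeder cells could not be separated in the deposited tables.

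The authors deposited a table of expected counts (reads per gene, not scaled to depth) and a table of RPKM (reads scaled to gene length and library size), both per library. The aligner and the read counter are not given in the sources used here, and the genome build was GRCh37.p13 per the submitters' processing notes. The count table held 27772 rows. In it 41.43% of the cells held a floor value of 0.05, read here as 0. Another 0.9142% of all cells lay above the floor and held fractions of shared reads, which were rounded. The 42 symbols present on 2 rows were summed, which left 27730 symbols, of which 23952 matched RefSeq symbols or synonyms. For genes with over 200 reads in every library, the ratio of count to RPKM stayed within 2% of one length in 65.03% of 6054 rows. No coordinates are given, since the reference at hand is of another build. Library totals ranged from 9223026 to 10118260 reads.

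Counts were analysed in R 4.3.3 with edgeR 4.0.16. Each of the 3 comparisons (AA147 with RP22 at day 13, RP22 with day 1, AA147 with day 1) was fitted on its own 6 libraries with group as the only term, after filterByExpr and TMM normalization, by the robust quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The biological coefficient of variation was 15.4% for AA147 with RP22, 15.6% for RP22 with day 1 and 12.3% for AA147 with day 1. The 2 comparisons with day 1 share their controls. CPM values (counts scaled to library size) are means over the 3 libraries of a group with their SD, scaled within the comparison. All p-values rest on the 3 replicates of each group being independent experiments, as the labels state.

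Fold changes against a group with no reads are lower bounds, computed against a floor of 3 reads over the group's 3 libraries. Where a group had 1 to 3 reads, the ratio is given with a 95% counting interval. Intervals and floors cover counting error only. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic of the test. Where a group had few reads, this SE can be smaller than the counting error of those reads alone, as for SNAI2 with AA147 against day 1. It then overstates the precision of the fold change.

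The 30 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover ATF6 targets, XBP1s targets, PERK and integrated stress response targets, heat shock, NRF2 and p53 targets, cholesterol synthesis, glycolysis and hypoxia, proliferation, pluripotency, markers of germ layers and cell types, mitochondrial DNA encoded genes and histone genes. Lists with at least 5 genes past the count filter were tested by camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation was run as an alternative. The mean log2 CPM of each list per library used a prior count of 2, and an exact two-sided permutation test of such means cannot go below 0.1 with 3 against 3 libraries. The genes named are taken from the 10 largest rises and falls past the test with groups that did not overlap and a mean of at least 5 CPM in the higher group, up to 4 members of each list past the test, and HSPA5, HSP90B1, ATF6, XBP1, POU5F1, NANOG, T and PECAM1. Some genes that meet this rule are not reported here.

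The procedure was tested on simulated data, drawn from negative binomial distributions with the observed levels and dispersions and with known changes. The edgeR test found 38.8% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 93.9% of those changed 4-fold in the design of AA147 with RP22, with 11 false calls among 13909 unchanged genes, 7.28% of its calls. In the designs against day 1 it found 62.1% and 69.7% of genes changed 2-fold, with 7.53% and 8.59% false calls. For AA147 with RP22, 13909 of 14121 simulated genes were unchanged, whereas 62.0% of genes passed in the data. TMM was not tested under a shift of many genes, so these rates may not hold for the data. False calls there were 23.2% with DESeq2, 14.7% with a replicate block, 4.51% with limma on log2 RPKM and 1.55% with limma-voom.

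Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, no count filter, all 9 libraries in one fit, a replicate block, a test against a 1.5-fold change, thinning to the smallest library, limma on log2 RPKM with a pseudocount of 1 or 0.1 and with or without a filter, fry, and leaving out each library in turn. Scaling by library totals alone and leaving out replicate 1 of both groups were added after seeing the data. Figures were drawn with matplotlib.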

Results

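RNA was sequenced from HUES9, a human embryonic stem cell line, before and after differentiation in the presence of either of 2 small molecules. AA147 is described in the study's labels as an activator of ATF6, a transcription factor of the unfolded protein response of the endoplasmic reticulum, and RP22 as its inactive analog. The 9 libraries fall into 3 groups of 3, namely untreated cells at day 1, cells at day 13 with 10 µM AA147, and cells at day 13 with 10 µM RP22. The labels call the 3 replicates of each group independent experiments. Library totals ranged from 9223026 to 10118260 reads, and 18243 of 27730 gene symbols had a read in at least 1 library.

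The groups separated along the first 2 principal components of log2 CPM (read counts scaled to library size), which held 64.6% and 28.7% of the variance. The 10 genes with the most reads took 8.06 to 8.98% of all reads in the AA147 libraries, 2.45 to 4.48% in the RP22 libraries and 2.31 to 2.41% at day 1. In the AA147 libraries the gene with the most reads was FN1, which encodes fibronectin, with 1.69 to 1.94% of the reads. RP22 replicate 1 stood apart from RP22 replicates 2 and 3, since the chi-square per degree of freedom over genes was 29.4 and 28.3 against them and 2.46 between replicates 2 and 3. Replicate 1 also lay further from replicates 2 and 3 than these from each other with AA147 (10.5 and 11.1 against 5.31) and at day 1 (14.6 and 8.90 against 3.81). The list means of RP22 replicate 1 differed in the same way, with a neural progenitor mean of 3.29 log2 CPM against 5.51 and 5.57, and an extracellular matrix mean of 10.02 against 8.56 and 8.69.

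**Figure D1:**
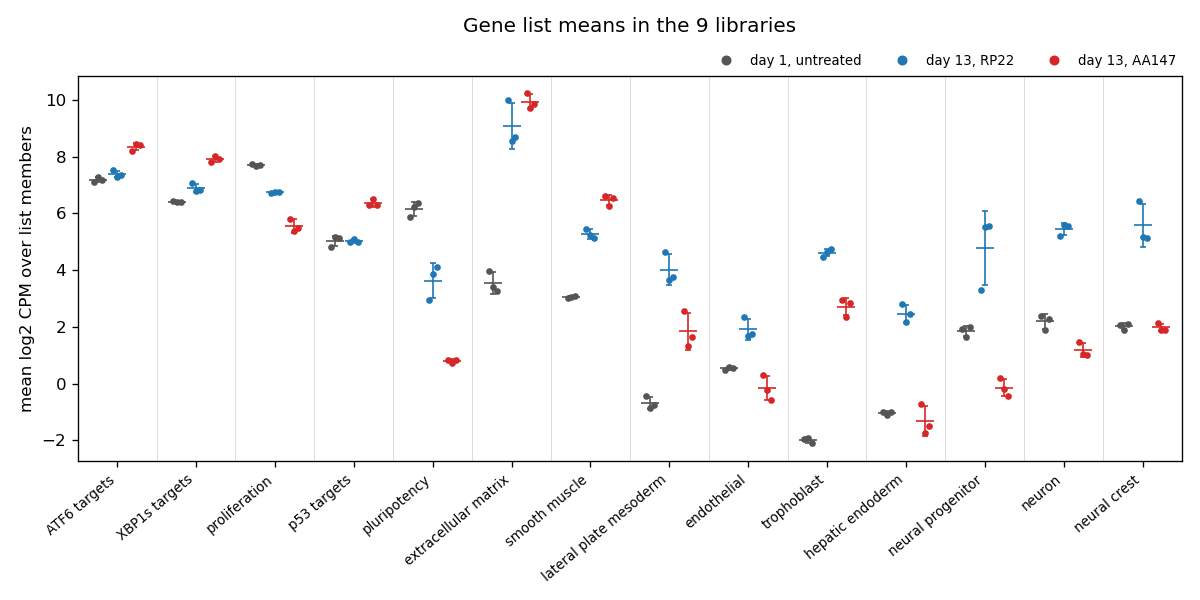
Mean log2 CPM over the members of 14 gene lists (vertical axis) in each of the 9 libraries. Points are libraries, horizontal marks are group means and vertical bars are the SD of 3 libraries; the ATF6 target means were 8.22 to 8.44 with AA147, 7.29 to 7.52 with RP22 and 7.10 to 7.28 at day 1.

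The comparison of AA147 with RP22 at day 13 asks how the ATF6 activator changed differentiated cultures relative to its inactive analog at the same dose and day. Most tested genes of protein folding in the endoplasmic reticulum and of smooth muscle were higher with AA147. Most tested genes of pluripotency, of the nervous system, of the endothelium, of hepatic endoderm and of cell division were lower. Of 14293 genes tested, 4265 rose and 4600 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). Changes of at least 2-fold counted 1201 genes upward and 2588 downward, and changes of at least 8-fold counted 53 upward and 918 downward. The balance of the calls depended on scaling, since 48.1% of them were upward with TMM normalization and 18.2% with library totals alone, where the median log2 fold change of all genes moved from -0.03 to -0.49. In 69.9% of the tested genes the 3 libraries of one group all lay above the 3 of the other, against 10% by chance.

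All 12 measured ATF6 targets, mostly chaperones and folding enzymes of the endoplasmic reticulum, rose with AA147, with a median log2 fold change of 0.88. The chaperone HSPA5 (BiP) went from 849 ± 73.4 to 1654 ± 134.9 CPM (SD, n = 3), a log2 fold change of 0.96 ± 0.0996 (SE). Other members were HSP90B1 (0.83 ± 0.121, 2328 against 1308 CPM), HERPUD1 (1.21 ± 0.0775, 117 against 50.6 CPM), MANF (0.99 ± 0.0845, 129.7 against 65.2 CPM) and DNAJB11 (0.77 ± 0.0601, 177 against 104 CPM), each given as log2 fold change ± SE and mean CPM with AA147 against RP22. The adjusted p of these 5 genes was 0.00065 or below (edgeR quasi-likelihood test, Benjamini-Hochberg). All 12 XBP1s targets, which serve secretion and degradation of proteins, also rose (median 0.93), among them DNAJB9 (1.23 ± 0.0987), SEC61A1 (1.23 ± 0.101) and SSR3 (1.12 ± 0.0974). The camera list test gave adjusted p = 1.4e-05 for the ATF6 targets and 1.4e-05 for the XBP1s targets, and adjusted p = 0.34 for both with an estimated correlation. Adjusted over the list alone, 12 members of the first list and 12 of the second were higher. XBP1 (0.87 ± 0.0776) mRNA rose as well, with an edgeR adjusted p of 6.6e-05. ATF6 mRNA itself was higher with TMM normalization (0.36 ± 0.0735) and not with library totals alone, where its log2 fold change was -0.10.

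The other stress lists moved less uniformly. Of 14 targets of PERK and the integrated stress response, 6 rose and 1 fell (5 and 1 adjusted over the list alone), and the list did not pass the camera test (adjusted p = 0.067). It passed with a replicate block (0.034), without AA147 replicate 1 (0.015), without RP22 replicate 2 (0.044) or 3 (0.039), and without replicate 1 of both groups (0.039). Its members that rose included ATF3 (1.25 ± 0.146, 139.7 against 58.5 CPM) and SESN2 (1.06 ± 0.106, 75.9 against 36.3 CPM). The heat shock list had 7 members higher and 1 lower of 10 (7 and 2 adjusted over the list alone), with a median of 0.40 that turned to -0.05 with library totals alone. Its camera adjusted p was 0.017, and adjusted p = 0.29 with an estimated correlation and 0.087 with library totals alone. The small heat shock protein HSPB1 (1.65 ± 0.0789, 351 against 112 CPM) and the cochaperone BAG3 (1.01 ± 0.0957, 93.4 against 46.4 CPM) rose. Of 10 NRF2 targets of the oxidative stress response, 7 rose and 2 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.0052, and adjusted p = 0.31 with an estimated correlation), with TXNRD1 (1.28 ± 0.0933), SRXN1 (1.46 ± 0.103) and ME1 (2.25 ± 0.16) among the higher. The adjusted p of the 7 genes named here was 0.00027 or below (edgeR quasi-likelihood test, Benjamini-Hochberg).

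Transcripts of the undifferentiated state were lower with AA147 than with RP22 at day 13. Of 12 pluripotency genes tested, 11 fell and 1 rose (the same numbers adjusted over the list alone), with a median of -3.28. POU5F1 (OCT4) had 10 reads over the 3 AA147 libraries and 698 over the 3 RP22 libraries, a log2 fold change of -5.58 ± 0.706. LIN28A (-4.19 ± 0.411, 10.3 against 189 CPM) and DNMT3B (-2.37 ± 0.302, 21.4 against 111 CPM), a DNA methyltransferase of early embryonic cells, were lower too. Without AA147 replicate 1 the log2 fold change of LIN28A was -4.81. The 3 genes had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.00095 or below. The list had a camera adjusted p = 0.0013, and adjusted p = 0.34 with an estimated correlation. NANOG did not pass the count filter, with 0 reads over the AA147 libraries and 80 over the RP22 libraries. Of 8 primitive streak genes, 7 fell and 1 rose (the same adjusted over the list alone; median -4.93, or -4.83 with members at 0 set to their bound). T (brachyury) had no reads with AA147 and 231 with RP22, so it was at least 54.6-fold lower against a floor of 3 reads over the group's 3 libraries, whereas LHX1 (2.31 ± 0.277) was higher. This list had a camera adjusted p = 0.0097, which was 0.34 as an adjusted p with an estimated correlation and 0.073 with library totals alone.

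The lowest list medians were those of neural progenitor and neuron genes. Of 11 neural progenitor genes, 9 fell and none rose (10 fell adjusted over the list alone), with a median of -6.90, or -6.66 with members at 0 set to their bound. The transcription factors ZIC1 (-6.66 ± 0.333, 0.579 against 59.4 CPM), ZIC2 (-8.04 ± 0.809, 0.252 against 68.2 CPM) and OTX2 (-8.07 ± 0.837, 0.205 against 58.7 CPM) were lower in all 3 AA147 libraries. Replicate 1 held 4 of the 5 AA147 reads of OTX2, and the log2 fold change was -7.53 for ZIC1 without it and -7.44 for ZIC2 without AA147 replicate 3. Of 11 neuron genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone; median -6.28), including the microtubule proteins DCX (-7.53 ± 0.262, 1.13 against 208 CPM) and STMN2 (-6.28 ± 0.14, 2.97 against 233 CPM). The adjusted p of these 5 genes was 0.00052 or below (edgeR quasi-likelihood test, Benjamini-Hochberg). Of 10 neural crest genes, 8 fell and 1 rose (the same adjusted over the list alone; median -4.91). SOX10 fell, with 1 read against 2265, a ratio of 1624 (95% counting interval 291 to 64155) in favour of RP22, and 1294 of the RP22 reads were in replicate 1. Camera adjusted p values were 4.6e-05, 1.1e-16 and 0.0076 for the 3 lists, and adjusted p = 0.34, 0.088 and 0.46 with an estimated correlation.

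Among the 10 largest falls past the test with groups that did not overlap, ISLR2 was at least 177-fold lower with AA147 against the floor, EOMES at least 130.3-fold, RFX4 at least 118-fold and INSC at least 113-fold lower, where 278 of the 464 RP22 reads of INSC were in replicate 1. ELAVL4 had 1 read with AA147, a ratio of 1938 (95% counting interval 347 to 76555) in favour of RP22. WNT8B was at least 554-fold lower, NEUROD1 at least 379-fold, FEZF2 at least 171-fold and FEZF1 at least 139-fold lower. These last 4 calls each ended when 1 library was left out (edgeR adjusted p, Benjamini-Hochberg). This was RP22 replicate 3 for WNT8B (0.058), RP22 replicate 2 (0.062) or 3 (0.089) for NEUROD1, and AA147 replicate 1 or 3 or RP22 replicate 2 or 3 for FEZF2 (0.053 to 0.099) and FEZF1 (0.055 to 0.096). The FEZF2 call also ended with limma-voom (0.051).

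Mesodermal lists moved in both directions. Smooth muscle and pericyte genes were mostly higher with AA147, with 7 of 10 higher and 1 lower (the same adjusted over the list alone), a median of 1.00, a camera adjusted p = 3.3e-06, and adjusted p = 0.088 with an estimated correlation. The contractile proteins ACTA2 (3.35 ± 0.133, 754 against 74.1 CPM), TAGLN (2.83 ± 0.113, 2029 against 286 CPM) and CNN1 (3.51 ± 0.135, 333 against 29.1 CPM) rose. Of 11 lateral plate and cardiac progenitor genes none rose and 9 fell (the same adjusted over the list alone; median -3.31), with BMP4 (-2.72 ± 0.326, 8.01 against 52.7 CPM) and PDGFRA (-3.61 ± 0.63, 6.25 against 76.2 CPM) among them. Of 12 endothelial genes none rose and 10 fell (the same adjusted over the list alone; median -2.88), among them CDH5 (-3.73 ± 0.476, 0.963 against 12.7 CPM), which encodes VE-cadherin, and VWF (-2.76 ± 0.509, 0.287 against 2.01 CPM). Without AA147 replicate 1, which held 4 of the 7 AA147 reads of VWF, the log2 fold change was -4.32 for PDGFRA, and without AA147 replicate 2 it was -4.35 for CDH5. The 7 genes had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.005 or below. The lateral plate list had a camera adjusted p = 0.023, which was an adjusted p = 0.46 with an estimated correlation, 0.17 with library totals alone and 0.054 without RP22 replicate 1. The endothelial list had a camera adjusted p = 0.0092, which was an adjusted p = 0.35 with an estimated correlation and 0.091 with library totals alone. PECAM1, another endothelial gene, had 29 reads in the RP22 libraries and none in the other 6, and did not pass the count filter.

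Cardiomyocyte genes did not move together, with 3 higher and 3 lower of 12 (the same adjusted over the list alone) and a camera adjusted p = 0.68. NPPB (3.35 ± 0.333, 127 against 12.4 CPM) and MYL7 (2.42 ± 0.253, 158 against 29.5 CPM) rose, whereas MYH6 had 1 read with AA147 and 485 with RP22, a ratio of 348 (95% counting interval 62.1 to 13759). Of 7 paraxial mesoderm genes, 3 rose and 4 fell (the same adjusted over the list alone; camera adjusted p = 0.47), with FOXC1 (1.05 ± 0.153) higher and PAX3 (-5.71 ± 0.777) lower. The cartilage and bone list had 1 member higher and 4 lower of 7 (1 and 5 adjusted over the list alone; camera adjusted p = 0.067), with RUNX2 (2.01 ± 0.215) higher and COL2A1 (-1.69 ± 0.191, 99.5 against 320.1 CPM) lower. This list passed camera without RP22 replicate 1 (0.00056), without AA147 replicate 1 (0.04) or 3 (0.031), without replicate 1 of both groups (0.0026), with a replicate block (0.017) and with all 9 libraries in one fit (0.018). Skeletal muscle, blood and gut endoderm lists had 3 genes each past the count filter, too few for a list test. In the skeletal muscle list ACTA1 (2.31 ± 0.426) was higher and MYH3 (-1.06 ± 0.321) lower, and the MYH3 call ended without AA147 replicate 2 or 3 or RP22 replicate 2 or 3 (adjusted p = 0.06 to 0.093). In the blood list RUNX1 (2.07 ± 0.0747) was higher and LMO2 (-4.47 ± 0.526) lower, and in the gut list all 3 genes were lower, among them CDX2 (-4.31 ± 0.687) and CDX1 (-0.79 ± 0.25). The CDX1 call ended with DESeq2 (0.066), all 9 libraries in one fit (0.089) and a replicate block (0.0501), and without AA147 replicate 2 or 3 or RP22 replicate 2 or 3 (0.054 to 0.1). Of the AA147 reads, 11 of 11 for PAX3, 8 of 9 for CDX2 and 4 of 7 for LMO2 were in replicate 1. Without AA147 replicate 3 the log2 fold change was -5.10 for PAX3 and -3.71 for CDX2. The 12 genes named with a log2 fold change had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.025 or below.

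Of 14 mesenchyme and extracellular matrix genes, 7 rose and 1 fell (the same adjusted over the list alone; median 1.24; camera adjusted p = 0.0076, and adjusted p = 0.46 with an estimated correlation). The matrix mean of RP22 replicate 1, 10.02 log2 CPM, lay within the AA147 range of 9.73 to 10.24 (exact permutation p = 0.3). FN1 went from 4555 ± 481 to 21603 ± 1459.7 CPM (SD, n = 3), and FBN1 (2.98 ± 0.154, 1234 against 156 CPM) and SPARC (2.08 ± 0.277, 3906 against 921 CPM) rose as well. The 10 largest rises past the test with groups that did not overlap included the activin subunit INHBA (4.30 ± 0.144, 196 against 9.96 CPM), ANKRD1 (3.94 ± 0.174, 1119 against 73.1 CPM), TGFBI (3.83 ± 0.199, 3392 against 238 CPM), and the basement membrane collagens COL4A3 (3.92 ± 0.282, 15.8 against 1.03 CPM) and COL4A4 (4.67 ± 0.223, 117 against 4.59 CPM). Others were GPR116 (4.80 ± 0.434), HTR1F (4.04 ± 0.384) and HSPB7 (3.83 ± 0.447). The 11 genes had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.00083 or below.

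Hepatic and trophoblast lists were lower with AA147. Of 11 hepatic and yolk sac genes none rose and 10 fell (the same adjusted over the list alone; median -5.34, or -5.00 with members at 0 set to their bound), with the apolipoproteins APOA1 (-7.44 ± 0.542, 0.249 against 45 CPM) and APOB (-6.71 ± 0.47, 0.284 against 31.3 CPM) among them. All 6 AA147 reads of APOA1 were in replicate 1, and its log2 fold change was -6.84 without AA147 replicate 3. The definitive endoderm list had 2 higher and 6 lower of 10 (the same adjusted over the list alone) and a camera adjusted p = 0.087, which was 0.023 without RP22 replicate 1 and 0.026 with a replicate block. CXCR4 (-6.70 ± 0.694, 0.246 against 26.8 CPM) was lower, while the epithelial genes CLDN6 (1.43 ± 0.0829, 791 against 294 CPM) and EPCAM (1.14 ± 0.137, 368 against 167 CPM) were higher. Of 10 trophoblast genes, 2 rose and 7 fell (the same adjusted over the list alone; median -3.09), with CYP19A1 (-2.95 ± 0.132, 5.07 against 39.2 CPM) and CGB5 (-3.24 ± 0.384, 3.57 against 33.8 CPM) lower. The surface ectoderm list had 4 higher and 2 lower of 10 (the same adjusted over the list alone; camera adjusted p = 0.13), and its median of 0.09 turned to -0.37 with library totals alone, although the keratins KRT8 (1.47 ± 0.0876, 2434 against 879 CPM) and KRT18 (1.38 ± 0.077, 1880.0 against 721 CPM) rose. The hepatic and trophoblast lists had camera adjusted p values of 1.4e-05 and 0.0076, and adjusted p = 0.34 and 0.29 with an estimated correlation. The 9 genes had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.00049 or below.

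Cell division genes fell and p53 targets rose. All 12 proliferation genes were lower with AA147 (median -1.30), among them TOP2A (-1.79 ± 0.133, 132 against 456 CPM) and BIRC5 (-1.45 ± 0.143, 22.8 against 62.4 CPM). Of 10 p53 targets, 9 rose and none fell (10 rose adjusted over the list alone; median 1.16), including the cell cycle inhibitor CDKN1A (2.59 ± 0.132, 605 against 101 CPM), the death receptor FAS (2.48 ± 0.133, 47.5 against 8.52 CPM) and RRM2B (1.42 ± 0.105, 185 against 69.2 CPM). Of 13 cholesterol synthesis genes, 10 rose and none fell (the same adjusted over the list alone; median 0.50), with MSMO1 (1.31 ± 0.118, 237 against 95.9 CPM) among them. The camera adjusted p of these 3 lists was 3.3e-06, 7.8e-06 and 0.01, and adjusted p = 0.34, 0.29 and 0.46 with an estimated correlation. The glycolysis and hypoxia list had 3 higher and 2 lower of 10 (the same adjusted over the list alone; camera adjusted p = 0.45), with a median of 0.25 that turned to -0.20 with library totals alone. In it EGLN3 (1.98 ± 0.161) was higher and VEGFA (-0.83 ± 0.103) lower. The 8 genes had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.00029 or below. Mitochondrial DNA encoded genes were not in the table with reads, and 4 of the histone genes without poly(A) tails passed the filter with none past the test. The histone gene HIST1H2AC passed the edgeR test as higher in 3 other settings. Its log2 fold change was 0.62 with a replicate block (adjusted p = 0.029), 0.98 without RP22 replicate 1 (0.0010) and 0.87 without replicate 1 of both groups (0.00016).

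**Figure D2:**
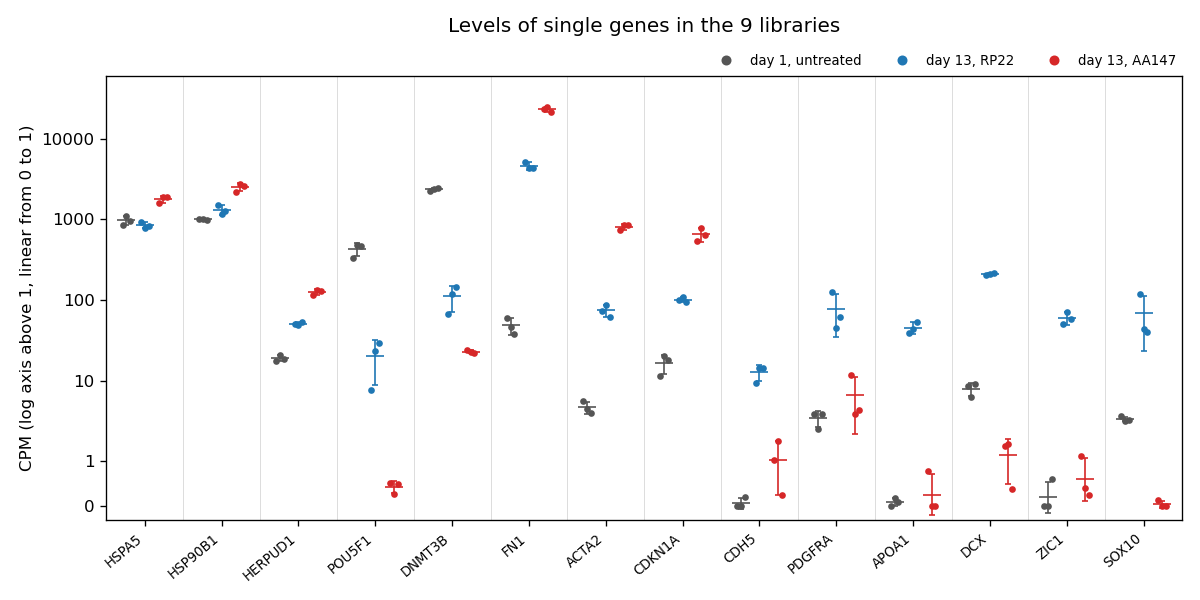
CPM of 14 genes (vertical axis, logarithmic above 1 CPM and linear from 0 to 1) in each of the 9 libraries, scaled over all 9. Points are libraries, horizontal marks are group means and vertical bars are the SD of 3 libraries; HSPA5, FN1, ACTA2 and CDKN1A were highest with AA147, and CDH5, APOA1, DCX, ZIC1 and SOX10 were highest with RP22.

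The comparison of RP22 at day 13 with untreated day 1 cells describes differentiation in the presence of the inactive analog. Pluripotency and cell division genes fell, while markers of all 3 germ layers and of trophoblast rose. Of 14558 genes tested, 5333 rose and 5129 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). With a threshold of 8-fold, 1225 genes were higher and 150 lower. In 76.9% of the tested genes the groups did not overlap, against 10% by chance.

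Of 16 pluripotency genes, 12 fell and 2 rose (the same adjusted over the list alone; median -3.13; camera adjusted p = 6.7e-06, and adjusted p = 0.31 with an estimated correlation). POU5F1 went from 481 ± 91.2 to 22.8 ± 12.7 CPM (SD, n = 3), and NANOG (-3.37 ± 0.48, 2.63 against 27.5 CPM), LIN28A (-3.16 ± 0.123, 214 against 1915 CPM) and DPPA4 (-3.41 ± 0.156, 97 against 1033 CPM) fell. Of 12 proliferation genes, 10 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 7.4e-05, and adjusted p = 0.12 with an estimated correlation), with BUB1 (-2.46 ± 0.0806, 90.9 against 499 CPM) and CCNB2 (-1.11 ± 0.0695, 72.8 against 157 CPM) among the lower. The 6 genes had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.00069 or below. The largest falls past the test were in HES3 (-7.75 ± 0.416), IDO1 (-6.60 ± 0.535), PPP1R1B (-6.51 ± 0.421), ADRA2A (-6.14 ± 0.336), NMRK2 (-6.12 ± 0.382), LECT1 (-5.98 ± 0.197) and TNFSF11 (-5.81 ± 0.527), with an adjusted p of 5.3e-05 or below in the same edgeR test. RP22 replicate 3 held 8 of the 10 RP22 reads of HES3 and 3 of the 4 of TNFSF11, and without it the log2 fold change was -7.51 for IDO1 and -6.71 for NMRK2. TRIM54, DAZL and UTF1 had 3, 1 and 2 reads in the RP22 libraries, with ratios of 236 (95% counting interval 80.4 to 1147), 167 (95% counting interval 29.5 to 6636) and 82.9 (95% counting interval 22.6 to 691) in favour of day 1. RP22 replicate 3 held 2, 1 and 2 of these reads.

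Of the mesodermal lists, 7 passed camera as higher from day 1 to day 13 with RP22, and the endothelial list did not. All 11 lateral plate and cardiac progenitor genes tested were higher (median 6.36), for example TBX3 (8.51 ± 0.293, 123 against 0.324 CPM) and ISL1 (6.36 ± 0.39, 42.4 against 0.496 CPM). The log2 fold change of ISL1 was 7.19 without day 1 replicate 1. In the paraxial list 5 of 6 rose and none fell (median 4.68), in the cardiomyocyte list 7 of 11 rose and none fell (median 3.76), and in the smooth muscle list 8 of 10 rose and none fell (median 2.31), with FOXC1 (5.22 ± 0.399, 12.6 against 0.326 CPM), MYL7 (6.98 ± 0.422, 33.4 against 0.25 CPM) and ACTA2 (3.99 ± 0.178, 83.9 against 5.24 CPM) as examples. Of 8 primitive streak genes 8 rose (median 4.40), with T at 231 reads against 1, a ratio of 213 (95% counting interval 37.9 to 8453). Matrix genes rose in 13 of 14 cases (median 5.42), and FN1 went from 54.1 ± 12.4 to 5154 ± 565 CPM (SD, n = 3). The cartilage and bone list had 6 higher and 1 lower of 7 (median 3.90), with COL2A1 (6.66 ± 0.236, 362 against 3.59 CPM) higher. Camera adjusted p values were 5.6e-05, 0.033, 0.012, 0.00099, 0.0036, 6.7e-06 and 0.0029 in this order, and adjusted p = 0.33, 0.26, 0.19, 0.12, 0.35, 0.4 and 0.14 with an estimated correlation. With all 9 libraries in one fit the paraxial list did not pass (adjusted p = 0.085). The member counts of these 7 lists were the same adjusted over the list alone. Of 11 endothelial genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.16), with CDH5 at 435 reads against 2, a ratio of 201 (95% counting interval 55.2 to 1662). Day 1 replicate 3 held 2 of the 2 day 1 reads of CDH5. The skeletal muscle list, too small for a list test, had none of 4 genes higher and 1 lower (none adjusted over the list alone; median -0.53), and the blood and gut lists, of 3 genes each, had 2 higher and none lower and 2 higher and 1 lower. The skeletal muscle call, MYH3, ended with DESeq2 (adjusted p = 0.075) and with library totals alone (edgeR adjusted p = 0.074). It also ended without day 1 replicate 2 or 3 or RP22 replicate 1 or 2 (edgeR adjusted p = 0.078 to 0.16). The 7 genes named with a log2 fold change or CPM had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 1.3e-05 or below.

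Endodermal, ectodermal and trophoblast genes rose as well. Of 11 hepatic genes 10 rose and none fell (median 5.02), with FGB at least 404-fold higher against the floor and APOA1 at a ratio of 474 (95% counting interval 162 to 2299). All 10 trophoblast genes rose (median 8.87, or 8.22 with members at 0 set to their bound), for example GATA3 (8.31 ± 0.223, 107 against 0.32 CPM) and CYP19A1 (7.85 ± 0.252, 44.4 against 0.181 CPM). This list held with an estimated correlation (camera adjusted p = 0.034). All 11 neuron genes rose (median 3.87), with DCX (4.72 ± 0.132, 235 against 8.93 CPM) among them, and 8 of 10 neural crest genes rose with none lower (median 3.25), with SNAI2 (8.40 ± 0.691, 89.7 against 0.256 CPM) among them. Of 10 surface ectoderm genes 6 rose and 1 fell, with KRT8 (2.59 ± 0.0849, 994 against 165 CPM) higher. Camera adjusted p values of the hepatic, neuron, neural crest and surface ectoderm lists were 0.0001, 4.1e-06, 0.006 and 0.0079, and adjusted p = 0.29, 0.12, 0.43 and 0.26 with an estimated correlation. Neural progenitor genes had 7 higher and 2 lower of 12 (8 and 2 adjusted over the list alone), and a camera adjusted p = 0.094, which was 2.2e-06 without RP22 replicate 1, 1.4e-05 without replicate 1 of both groups and 0.0052 with a replicate block. Of the day 1 reads, 3 of 5 for CYP19A1 were in replicate 2 and 4 of 7 for SNAI2 in replicate 3. The definitive endoderm list had 8 higher and 2 lower of 10, and a camera adjusted p = 0.078, which was 0.011 without RP22 replicate 1 and 0.026 with a replicate block. The other lists of this paragraph had the same member counts adjusted over the list alone, and the 5 genes with a log2 fold change had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 9.8e-05 or below.

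The largest rises with RP22 against the floor were in S100A9 (at least 1484-fold higher), CYP24A1 (at least 1104-fold), RGS4 (at least 1148-fold), RSPO3 (at least 716-fold), MMRN1 (at least 699-fold) and NEUROD1 (at least 487-fold). CGA, the alpha subunit of chorionic gonadotropin, had 10629 reads against 1, a ratio of 9806 (95% counting interval 1759.5 to 387334). FMOD was at least 1598-fold and EMX2 at least 850.5-fold higher, and DCN had a ratio of 5461 (95% counting interval 979.8 to 215748). These last 3 calls ended without day 1 replicate 1, with edgeR adjusted p (Benjamini-Hochberg) of 0.07, 0.061 and 0.052. With limma-voom those of FMOD (0.058) and EMX2 (0.08) ended too, and with all 9 libraries in one fit that of FMOD (0.052). Of the RP22 reads, 4082 of 5032 for FMOD, 4581 of 5920 for DCN and 2427 of 3647 for RGS4 were in replicate 1.

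Stress lists were mixed from day 1 to RP22. Of 12 ATF6 targets 3 rose and 1 fell (the same adjusted over the list alone; median 0.02; camera adjusted p = 0.64), with HERPUD1 (1.42 ± 0.1, 57.3 against 21.4 CPM) higher and HYOU1 (-0.46 ± 0.0652, 321 against 441 CPM) lower. HSPA5 had a log2 fold change of -0.18 ± 0.112 that did not pass the edgeR test (adjusted p = 0.19, Benjamini-Hochberg), and without replicate 1 of both groups it was -0.34 and passed (adjusted p = 4.8e-05). In the XBP1s list 8 rose and 2 fell (camera adjusted p = 0.17), with EDEM1 (2.17 ± 0.134, 90.7 against 20.2 CPM) higher. The PERK list had 2 higher and 7 lower (camera adjusted p = 0.19, 0.049 with a replicate block and 0.022 without replicate 1 of both groups), and the heat shock list 2 and 5 (camera adjusted p = 0.14), with ASNS (-1.38 ± 0.224, 125 against 325 CPM) and HSPD1 (-1.61 ± 0.0882, 365 against 1117 CPM) lower. Of 10 NRF2 targets 6 fell and none rose (camera adjusted p = 0.04, adjusted p = 0.55 with an estimated correlation, and 0.065 without day 1 replicate 2), with NQO1 (-2.18 ± 0.245, 29.2 against 132 CPM) lower. The p53, cholesterol and glycolysis lists had 1, 7 and 4 members higher and 3, 1 and 6 lower, with camera adjusted p values of 0.65, 0.16 and 0.073, with CDKN1A (2.63 ± 0.19, 114 against 18.5 CPM) and HMGCS1 (1.10 ± 0.103, 218 against 102 CPM) higher and ENO1 (-1.61 ± 0.0734, 630.0 against 1921 CPM) lower. Without day 1 replicate 1 the cholesterol and glycolysis lists reached 0.031 and 0.049, and without replicate 1 of both groups the cholesterol list reached 0.047. The member counts of the lists in this paragraph were the same adjusted over the list alone. The 9 genes that passed had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.0013 or below.

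The comparison of AA147 at day 13 with untreated day 1 cells describes differentiation in the presence of the activator. Pluripotency and cell division genes fell, and matrix, smooth muscle, trophoblast and endoplasmic reticulum genes rose. Of 13761 genes tested, 5323 rose and 5559 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). With TMM 48.9% of the calls were upward, and with library totals alone 34.3%, where the median of all genes was -0.48. In 82.4% of the tested genes the groups did not overlap, against 10% by chance.

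Of 15 pluripotency genes, 14 fell and 1 rose (the same adjusted over the list alone; median -7.88, or -6.85 with members at 0 set to their bound). POU5F1 went from 399.6 ± 76.3 to 0.405 ± 0.131 CPM (SD, n = 3), SOX2 (-10.21 ± 0.206, 0.539 against 646 CPM) and DNMT3B (-6.68 ± 0.101, 21.3 against 2188 CPM) fell, and NANOG was at least 187-fold lower. All 12 proliferation genes fell (median -2.18), including MCM5 (-3.02 ± 0.117, 32.1 against 260.2 CPM) and CCNB2 (-2.30 ± 0.0937, 26.4 against 130.1 CPM). Camera adjusted p values were 4.0e-13 and 4.9e-07, and adjusted p = 0.1 and 0.25 with an estimated correlation. The largest falls were in VRTN (at least 1605-fold lower), NMRK2 (at least 632-fold), C9orf135 (at least 483-fold), PPP1R1B (at least 376-fold), PREX2 (at least 196-fold), KCNG3 (at least 165-fold) and TDGF1 (-10.97 ± 0.42). The log2 fold change of SOX2 was -11.00 without AA147 replicate 2, and 3 of the 4 AA147 reads of TDGF1 were in replicate 3. PRDM14 and ZSCAN10 each had 1 read with AA147, with ratios of 2632 (95% counting interval 472 to 103994) and 3355 (95% counting interval 602 to 132550.5) in favour of day 1. The genes of this paragraph had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.00023 or below.

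Matrix genes rose in 13 of 14 cases and fell in 1 (median 6.46), with FN1 going from 44.9 ± 10.2 to 21489.7 ± 1460.1 CPM (SD, n = 3) and COL1A1 (6.27 ± 0.194, 12684 against 164 CPM) and FBN1 (6.95 ± 0.158, 1228 against 9.92 CPM) higher. Of 10 smooth muscle genes 8 rose and none fell (median 3.72), with ACTA2 (7.42 ± 0.132, 750.0 against 4.35 CPM) and TAGLN (4.84 ± 0.119, 2019 against 70.7 CPM) among them. All 7 trophoblast genes tested rose (median 8.85, or 7.77 with members at 0 set to their bound), with GATA3 (8.85 ± 0.188, 130.2 against 0.265 CPM) among them. Cardiomyocyte genes had 6 higher and 1 lower of 10 (median 2.92), with MYL7 (9.47 ± 0.227, 157 against 0.208 CPM) and NPPB (8.66 ± 0.211, 126 against 0.302 CPM) higher. Camera adjusted p values of these 4 lists were 3.0e-09, 5.5e-07, 7.8e-05 and 0.014, and adjusted p = 0.1, 0.1, 0.1 and 0.19 with an estimated correlation. Adjusted over the list alone, the cardiomyocyte list had 5 higher and 1 lower, and the other 3 lists had the same counts. The cardiomyocyte list did not pass with all 9 libraries in one fit (adjusted p = 0.35). The largest rises were in COL3A1 (11.79 ± 1.08), LUM (12.21 ± 0.51) and ITGB6 (12.15 ± 0.65), in ITGA11, HSD3B1, WNT6 and MFAP5 with ratios of 11535 (95% counting interval 2069.8 to 455671), 5452 (95% counting interval 978 to 215405), 6259 (95% counting interval 1123 to 247261) and 3559 (95% counting interval 1218 to 17264), and in CYP24A1, OLR1 and NNMT, which were at least 556-fold, 487-fold and 471-fold higher. Of the day 1 reads, 107 of 113 for COL3A1, 22 of 22 for ITGB6 and 6 of 6 for LUM were in replicate 1, without which the log2 fold change of COL3A1 was 15.33. That of NPPB was 9.36 without day 1 replicate 2, and 728 of the 1224 AA147 reads of CYP24A1 were in replicate 1. The OLR1 call ended without replicate 1 of both groups (edgeR adjusted p = 0.072, Benjamini-Hochberg), and for the genes of this paragraph the adjusted p was otherwise 0.0061 or below.

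All 12 ATF6 targets rose from day 1 to AA147 (median 0.96), and 11 of 12 XBP1s targets rose (11 higher and 1 lower adjusted over the list alone; median 1.39). Examples were HSPA5 (0.87 ± 0.112, 1646 against 903 CPM), HSP90B1 (1.32 ± 0.0924, 2317 against 927 CPM), HERPUD1 (2.71 ± 0.102, 116 against 17.7 CPM), SEC24D (2.45 ± 0.0951, 352 against 64.3 CPM) and EDEM1 (3.11 ± 0.0964, 145 against 16.8 CPM). Camera adjusted p values were 0.0039 and 1.4e-05, and adjusted p = 0.56 and 0.24 with an estimated correlation. The PERK, heat shock and NRF2 lists had medians of 0.27, 0.30 and 0.35 that turned to -0.17, -0.14 and -0.09 with library totals alone, and camera adjusted p values of 0.84, 0.97 and 0.97, with a camera statistic below 0 for the PERK and NRF2 lists. Of 10 p53 targets 7 rose and none fell (camera adjusted p = 0.081, 0.017 with a replicate block and 0.036 without replicate 1 of both groups), with CDKN1A (5.30 ± 0.231, 602 against 15.3 CPM) and MDM2 (1.46 ± 0.127, 353 against 129 CPM) higher. In the cholesterol list 11 of 13 rose and none fell (camera adjusted p = 0.062, 0.0065 without day 1 replicate 1, 0.033 without AA147 replicate 1, 0.0003 without both and 0.036 with all 9 libraries in one fit), with SQLE (1.58 ± 0.115, 227 against 76 CPM) higher. The glycolysis list had 3 higher and 6 lower (median -0.31, mean 0.0874, camera adjusted p = 0.67), with NDRG1 (3.76 ± 0.18, 47 against 3.46 CPM) higher and ENO1 (-1.40 ± 0.0872, 604 against 1596 CPM) lower. The 10 genes had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 6.1e-05 or below.

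Neural genes did not rise as a group. Of 7 neural progenitor genes none rose and 5 fell (median -4.61, or -4.36 with members at 0 set to their bound), with ZIC2 (-9.20 ± 0.336, 0.251 against 151 CPM) and OTX2 (-8.93 ± 0.51, 0.203 against 106 CPM) lower. The list had a camera adjusted p = 0.027, adjusted p = 0.22 with an estimated correlation, 0.059 with library totals alone and 0.34 with all 9 libraries in one fit. In the neuron list 1 rose and 2 fell of 7 (camera adjusted p = 0.81), with DCX (-2.73 ± 0.402, 1.12 against 7.42 CPM) and GAP43 (-5.48 ± 0.433, 0.979 against 44.2 CPM) lower. The neural crest list had 3 higher and 6 lower of 9, a median of -1.35 and a camera statistic of the opposite sign (adjusted p = 0.84), with SNAI2 (10.01 ± 0.179, 229 against 0.213 CPM) higher. The lateral plate list had 4 higher and 1 lower of 6 (camera adjusted p = 0.081, 0.039 with library totals alone, 0.042 without day 1 replicate 1 and 0.013 without replicate 1 of both groups), with HAND1 (7.24 ± 0.573, 237 against 1.52 CPM) higher. Of the day 1 reads of HAND1, 42 of 52 were in replicate 1, without which its log2 fold change was 8.97. Endothelial genes had 1 higher and 4 lower of 6 (camera adjusted p = 0.58, and 0.048 without replicate 1 of both groups), with KDR (-2.42 ± 0.525, 7.7 against 41.4 CPM) lower. The surface ectoderm list had 6 higher and 2 lower of 9 (camera adjusted p = 0.046, adjusted p = 0.23 with an estimated correlation, 0.052 without day 1 replicate 2 and 0.062 without day 1 replicate 3), with KRT8 (4.14 ± 0.0832, 2421 against 137 CPM) higher. The cartilage list had 4 higher and 2 lower of 6 (camera adjusted p = 0.68), with ALPL (-7.19 ± 0.217, 1.48 against 217 CPM) among the lower. The definitive endoderm list had 2 higher and 1 lower of 5 (camera adjusted p = 0.67), with GATA6 (6.34 ± 0.265, 27.7 against 0.325 CPM) higher. Primitive streak, paraxial, hepatic, skeletal muscle, blood and gut lists had too few genes past the filter for a list test, with 2, 3, 0, 2, 1 and 1 higher and 1, 0, 2, 1, 1 and 1 lower. Among them LHX1 (4.52 ± 0.281, 22.3 against 0.968 CPM) and FOXC1 (6.34 ± 0.304, 22.8 against 0.271 CPM) were higher and APOB (-3.46 ± 0.431) and MYH3 (-1.75 ± 0.316) lower. Without AA147 replicate 1, which held 4 of the 5 AA147 reads of OTX2, the log2 fold change was -6.85 for GAP43 and -3.12 for KDR. Without AA147 replicate 3 it was -8.59 for ZIC2, and day 1 replicate 3 held 4 of the 7 day 1 reads of SNAI2. The 14 genes had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.0056 or below. Apart from the cardiomyocyte and XBP1s lists, member counts with AA147 against day 1 were the same adjusted over the list alone.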

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

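Camera with the preset and the estimated correlation was chosen before the results were seen, and the library totals, the splits and the tests of explanations in this part after. The lists below had medians of opposite sign against day 1 with AA147 and with RP22, and they differed between the compounds by camera with the preset correlation. With an estimated correlation none of these differences passed. Against day 1, camera with the preset correlation passed for neural progenitor genes with AA147 and for neuron, neural crest and NRF2 genes with RP22, and for none of the other changes from day 1 given here. With an estimated correlation these 4 did not pass either (adjusted p = 0.22, 0.12, 0.43 and 0.55). The median log2 fold change of AA147 against RP22 was -6.90 for neural progenitor genes, which had medians against day 1 of 2.97 with RP22 and -4.61 with AA147. It was -6.28 for neuron genes (3.87 and -0.90), -4.91 for neural crest genes (3.25 and -1.35) and -2.88 for endothelial genes (1.72 and -1.99). It was 1.12 for NRF2 targets (-0.86 and 0.35), 1.16 for p53 targets (-0.14 and 1.17) and 0.40 for heat shock genes (-0.26 and 0.30). Medians against day 1 cover different members, since each comparison had its own filter. RP22 and AA147 had 12 and 7 neural progenitor, 11 and 7 neuron, 10 and 9 neural crest, and 11 and 6 endothelial genes. Over all members with reads, mean log2 CPM at day 1 and with AA147 was 1.85 and -0.14, 2.20 and 1.18, 2.03 and 1.98, and 0.53 and -0.16. Neural crest genes as a whole thus hardly changed with AA147. With library totals alone the heat shock difference turned to -0.05, and the medians with AA147 against day 1 turned to -0.09 for NRF2 and -0.14 for heat shock genes, the same sign as with RP22.

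The ATF6 targets were higher with AA147 than with RP22. Scaling alone is argued against by a list median of 0.42 with library totals, where 11 of the 12 members still rose. Matrix mRNA took 0.0965 to 0.108% of reads at day 1, 1.69 to 3.89% with RP22 and 5.86 to 6.85% with AA147. A rise of chaperone mRNA in proportion to it would give a median of 0.44 from day 1 to RP22. All 12 targets lay below their predicted change, by a median of -0.40. Part of this gap may come from scaling, since the matrix shares used library totals and the fold changes TMM. Library totals moved the median of all genes against day 1 from -0.04 to -0.48 with AA147 and from 0.02 to 0.12 with RP22. An effect of matrix load also stays open since RP22 replicate 1, with the most matrix reads of the RP22 libraries, had their highest ATF6 target mean (7.52 against 7.29 and 7.37 log2 CPM), and a response out of proportion was not tested. Activity of the compound, which the design names, stays open and was not tested apart from the differences between the cultures that came with it.

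RP22 replicate 1 stood apart from RP22 replicates 2 and 3, and replicate 1 of AA147 and of day 1 did so by smaller distances. If AA147 RNA had been mixed into it, 221 abundant genes that differ at least 4-fold between AA147 and RP22 replicates 2 and 3 would imply one common share, and the interquartile range of the shares, 0.146, lay under the limit of 0.2 set for this. However, the median share was 0.0192, and 38.0% of these genes moved away from AA147, over the limit of 20%, with COL3A1 at 0.57 and FN1 at 0.0459, so mixing is argued against as the whole cause. A condition shared by the replicate 1 cultures at day 13 stays open. The deviations of RP22 replicate 1 from its group mean correlated with those of AA147 replicate 1 across genes (r = 0.19). Its correlations with AA147 replicates 2 and 3 (-0.15 and -0.10) add nothing, since such deviations cancel out within a group. Both replicate 1 libraries lay apart from the other day 13 libraries on the third principal component (-31.9 and -27.6 against 11.8 to 19.8). Of the 6 day 13 libraries, 4 correlated best with their own number, the replicate 1 libraries among them. The others were AA147 replicate 3 and RP22 replicate 3. A condition of the replicate 1 cultures alone predicts nothing about these, so the count does not decide. No biological explanation was tested.

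Lineage lists were lower with AA147 than with RP22. Without the 100 genes with the most reads the neural progenitor median was -6.89. This cannot decide whether a few genes taking more of the reads played a part, since TMM already allows for such genes. Scaling by library totals alone moved the median of all genes only from -0.03 to -0.49, which is small beside the neural progenitor median of -6.90. Whether one expanding kind of cell diluted every other lineage alike was not settled. The medians of the 9 lower lists, from -6.66 to -2.88 with members at 0 set to their bound, spanned 3.78 log2 units. Dilution alike was expected to keep them within 1 log2 unit. A permutation of the 96 members of these lists over the lists gave p = 0.14 for the spread of the medians. This p cannot decide, since it takes the spread of members within a list as noise, whereas dilution alike would lower members alike too. A test of neural progenitor against lateral plate members alone, picked first because these medians lay far apart, had given a permutation p = 0.018. An effect of AA147 on differentiation, which the design names, stays open.

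With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and no more can be said on chance. The real split was the 1 of 10 with as many genes called in each comparison, with 8865 genes for AA147 against RP22, 10462 for RP22 against day 1 and 10882 for AA147 against day 1, and the highest of the other splits called 0 genes in each. Every other split put libraries of both groups on each side, which widens the spread within a side. Few calls were therefore likely there in any case, and the contrast adds no support.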

How the results depend on the processing

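Scaling by library totals and leaving out replicate 1 of both groups were chosen after seeing the data, and the other alternatives before. For AA147 against RP22, 4265 genes were higher and 4600 lower. A test against a 1.5-fold change called 1664 and 2488, fewer by construction. Library totals alone called 1897 and 8527, limma on log2 RPKM called 1869 and 7801 with a pseudocount of 1, 1866 and 7788 with 0.1, and 1873 and 9224 without a filter. Library totals alone and the limma fits on log2 RPKM do not apply TMM, which removes the shift of the all-gene median. Leaving out each library in turn gave 3754 to 4616 higher and 3767 to 4831 lower. For RP22 against day 1 the test against a 1.5-fold change called 3547 and 2563, with 4885 to 5420 and 4701 to 5195 on leaving out libraries. For AA147 against day 1 it called 3565 lower, with 5101 to 5451 and 5244 to 5587 on leaving out libraries. The calls of DESeq2, limma-voom, DESeq2 size factors, no count filter, all 9 libraries in one fit and thinned libraries stayed within 1.5 times the counts above in every comparison. With library totals AA147 against day 1 gave 3866 higher and 7416 lower. The lists past camera numbered 8 higher and 10 lower, 12 and 3, and 7 and 3 in the 3 comparisons. Camera with an estimated correlation left 0 and 0, 1 and 0, and 0 and 0, and the cause was not tested. Fry, which does not compare a list with other genes, called 5 lower lists for RP22 against day 1, and 13 higher and 5 lower for AA147 against day 1. Named genes were not tallied with no count filter, the test against a 1.5-fold change, thinned libraries, or log2 RPKM with a pseudocount of 0.1 or without a filter. In the other settings, 5309 values of named genes kept their direction and side of the threshold, 72 lost their call and 4 gained one. A missing adjusted p was counted as kept. For list tests, which were also run in only some settings, these numbers were 813, 54 and 55. Of the named genes past the test only ATF6 in AA147 against RP22 changed sign in the tallied settings. Its log2 fold change was -0.0865 with limma on log2 RPKM (adjusted p = 0.31) and -0.10 with library totals (adjusted p = 0.22). It passed the test in neither, and the cause was not tested beyond the missing TMM. Another 6 values of named genes that had not passed also crossed 0. Whether replicate numbers pair the libraries was not settled by correlations of 0.19, 0.15 and 0.0644 between AA147 and RP22 libraries of one number across genes. The replicate block called 4126 higher and 4548 lower, sharing 94.5% of the calls. With the block, the PERK list of AA147 against RP22 reached a camera adjusted p = 0.034, cartilage 0.017 and definitive endoderm 0.026. Depth limits genes near the floor, such as NANOG and PECAM1, which were not tested in AA147 against RP22.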

Other observations

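The gene groups and tests in this part were all chosen after the results were seen. One list held coat and cargo genes of COPII vesicles, the vesicles that carry proteins out of the endoplasmic reticulum. All 12 genes of this list were higher with AA147 than with RP22 (median 0.67, edgeR adjusted p of 0.034 or below). With library totals alone 6 were higher and 1 lower, and 11 or 12 were higher on leaving out each library in turn. KDELR3 (1.84 ± 0.279, 118 against 32.9 CPM), KDELR2 (1.21 ± 0.139, 632 against 274 CPM) and SEC23A (0.93 ± 0.121, 314 against 165 CPM) were examples, as log2 fold change ± SE and mean CPM with AA147 against RP22. Of 19 basement membrane genes, 12 were higher and 4 lower. COL4A1 (2.72 ± 0.112, 11003 against 1670.2 CPM) and LAMA5 (1.47 ± 0.0787, 995 against 360.2 CPM) were higher, whereas LAMA1 (-1.62 ± 0.205, 94.7 against 290.2 CPM), LAMA4 (-5.05 ± 1.11, 1.05 against 34.6 CPM) and NID2 (-3.28 ± 0.815, 36 against 349 CPM) were lower. Of the RP22 reads, 763 of 1154 for LAMA4 and 6954 of 11681 for NID2 were in replicate 1, without which their log2 fold changes were -4.00 and -2.48. Without AA147 replicate 1 they were -6.09 and -4.14, and without AA147 replicate 3 that of LAMA4 was -4.44 and the NID2 call ended (adjusted p = 0.058). On leaving out each library in turn, 12 basement membrane genes were higher and 2 to 4 lower. Of 15 HOX genes tested, 1 was higher, HOXA3 (1.64 ± 0.403), and 6 were lower, among them HOXB3 (-1.71 ± 0.412, 7.33 against 24.2 CPM) and HOXB4 (-1.75 ± 0.528, 2.58 against 8.73 CPM), and 4 to 8 were lower on leaving out each library in turn. The HOXB4 call ended without any 1 of the AA147 libraries (adjusted p = 0.074 to 0.081), and its log2 fold change was -0.92 without RP22 replicate 1. The named genes had edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.023 or below.

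A first hypothesis, prompted by CTGF, CYR61, ANKRD1 and TGFB2, is that targets of the YAP and TEAD transcription factors were higher with AA147 as a group. Of a list of 22 such genes, 21 were tested. Without the 4 genes that prompted it, the median log2 fold change over the other 17 was 1.16, with 16 higher and none lower, and 0.71 with library totals alone, where 13 were higher and 1 lower. On leaving out each library in turn the median was 1.05 to 1.60, with 13 to 16 higher and at most 1 lower. Over these 17 genes the camera adjusted p was 3.5e-09, and 0.045 with an estimated correlation, where the call ended on leaving out any 1 library (0.055 to 0.12). AXL (2.01 ± 0.0842, 401 against 99.4 CPM), CCDC80 (3.80 ± 0.236, 2473 against 177 CPM) and CRIM1 (1.72 ± 0.0909, 562 against 170.2 CPM) were examples. This pattern is consistent with a change in YAP and TEAD activity, but several of the genes are also matrix or growth factor targets of other pathways, which were not separated.

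A second hypothesis, prompted by GABRP and WNT6, is that amnion-type epithelium may contribute more RNA with AA147. Without these 2 genes, the other 8 members of a list of 10 had a median of 0.87, with 5 higher and none lower. With library totals alone the median was 0.42, with 4 higher and 1 lower, so the test did not decide. On leaving out each library in turn the median was 0.79 to 1.16. Its most abundant members were GABRP (2.33 ± 0.253, 3653 against 726 CPM), IGFBP3 (2.61 ± 0.153, 2695 against 441 CPM) and KRT7 (1.57 ± 0.107, 1421 against 479 CPM), while TFAP2A was at -0.01 ± 0.0978 and ISL1 at -0.19 ± 0.286. Of the 10 genes, 4 are also in lists fixed before the data were examined. IGFBP3 is also in the YAP and TEAD list, and without it the median over the other 7 genes was 0.48, or 0.42 to 1.08 on leaving out each library in turn, the highest without RP22 replicate 1.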
